A study of Gallus gallus with 6 samples.

How the data were processed

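Total RNA of blood leukocytes from 6 female chickens was labelled with Cy3 and hybridised to single-colour Agilent arrays, 1 bird per array, per the labels' protocols. The groups, wild type and heterozygous GFP transformant with 3 birds each, were taken from the source names in the labels, which also number the replicates 1 to 3. The titles and numbers are read as separate birds. The p-values thus set the group difference, which is also a slide difference, against the spread among these birds within a slide.

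The deposited scanner files hold spot intensity on a linear scale. Per the file headers they were made by Agilent Feature Extraction 12.0.3.1 with protocol GE1_1200_Jun14 on array design 026441, annotated on the chicken genome build galGal3. The processed signal is background-corrected and was not normalized between arrays, per the file headers. The deposited files also hold flags for each spot, read here as other values, for a signal well above background, for a positive and significant signal, for saturation and for outliers. The table of the whole series holds intensity too. In each column of the deposited table the value was the scanner's processed signal times a single factor, from 2.00 to 2.28, with log2 deviations of at most 7.18e-10, so it is linear and not centred. Its column medians were 296, 297 and 296 for wild type 1 to 3 and 298, 286 and 292 for GFP transformant 1 to 3. It was used as an alternative only.

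For the main setting, log2 of the processed signal was reduced by each array's 75th percentile over non-control spots. Spots of the same probe were averaged, control spots and outlier spots were left out, and 16 probes with no usable spot on some array were dropped. Probes well above background on at least 3 of the 6 arrays were kept, 28117 in all. Probes were named through their RefSeq accession, without version, in a RefSeq gene table of assembly GRCg7b, which was used for names and for which genes neighbour each other, and no coordinates are given because the array was annotated on another build. Of 43603 probes, 12261 matched a gene, 5543 genes in all, and the remaining 31342 probes stayed unnamed and were kept as features of their own. For a gene with several tested probes, as 2858 genes had, the probe with the highest mean over the 6 arrays stood for the gene. This left 22988 features, of which 4356 were genes with a symbol other than a LOC number.

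Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term and the Benjamini-Hochberg adjustment at 0.05. Fold changes are log2 values, transformant minus wild type, with the moderated standard error. A probe that no array of a group measured well above background has only a bound there, while one measured on some of its arrays keeps its log2 change: the mean of the bright group was set against the mean, over the dim group's arrays, of the higher of the lowest signal well above background and the probe's own signal, in normalized log2 values. Where the probe's own signal was the higher on all of these arrays, this value is the fold of the signals as measured. It then rests on signals not well above background in the dim group. A gene counted as not above background only if all its probes were. The statement in the series design that each triplet was compared by brute force was read as a count of features at least 2-fold apart in all 9 pairs. Gene lists, 8 of cell types and 16 of pathways, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the 24 lists. List names were matched by symbol and then by a synonym of a single gene, and 4 synonyms that led to another gene were dropped after the data were seen.

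The text names, for each direction, the 12 genes with the largest change among those past the threshold, filled up by the smallest unadjusted p where fewer passed, and 2 members of each list with the smallest p, or 4 for a list that passed. It also names the 5 genes with the largest measured gap over all 9 pairs, the 3 brightest genes detected in a single group, and the W-linked genes of the sex check. Some genes that meet this rule are counted but not reported here by name. This rule and the main tests were chosen before the data were examined.

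The fit was tested on simulated data with the measured means and spreads of the 22988 features, 200 of them changed. It called 80.6% of the features changed 4-fold, 46.3% of those changed 2-fold and 6.06% of those changed 1.5-fold, with 2.20% false calls among all calls and no wrong sign. The simulated noise was independent between features and held no slide effect, so this share of false calls does not carry over to the measured arrays. The alternatives were other scalings, filters and background corrections, other variance models, array weights, other rules for the probes of a gene, the replicate number as a block, other list tests and each bird left out. The normexp background correction was planned on mean spot signals. Mean spot signals were not used here, and median spot signals took their place, a form chosen after the data were seen. Normexp also added an offset of 50 units to each spot, where the arrays' median processed signal was 128 to 148 units. Such an offset shrinks the folds of dim features by itself. A block for slide could not be fitted, because each slide held a single group, and the scan followed the slide. Precision is limited by the number of arrays.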

Results

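Blood leukocytes of 6 female chickens aged 1 to 2 months were profiled on single-colour oligonucleotide arrays. Of these birds, 3 were wild type and 3 were heterozygous carriers of a green fluorescent protein (GFP) transgene, here called GFP transformants, and each array held the RNA of 1 bird. The leukocytes were the cells collected at the interface of a Ficoll density gradient, a step meant to remove most red cells and granulocytes. Each array carried 43803 non-control spots, of which between 62.4% and 66.1% were well above the local background, and the arrays' 75th percentile of signal lay between 898 and 1015 units. No non-control spot was saturated. The number of birds, 3 in each group, limits the precision of every value given here. All 3 wild type arrays were on slide 1 and all 3 transformant arrays on slide 2, each slide with its own scan, so slide and genotype cannot be told apart in any comparison between the groups.

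The sex given in the labels was checked first. HINTW, a gene of the female-specific W chromosome, was bright in both groups, at 7.22 ± 0.23 (SD, n = 3) in wild type and 7.23 ± 0.08 (SD, n = 3) in transformants on the log2 scale relative to each array's 75th percentile. The W-linked genes SPIN1L, HNRNPKL and UBAP2L2 differed by -0.22 (SE 0.09), -0.05 (SE 0.11) and 0.08 (SE 0.09) between the groups, with adjusted p-values of 0.218, 0.811 and 0.590 in limma. Of the other W-linked genes of the check, LOC427025 differed by 0.62 (SE 0.18, adjusted p = 0.122). SMAD7B, the W-linked copy of an inhibitor of TGF-beta signalling, rose by 1.23 (SE 0.16, adjusted p = 0.0102) in the transformants. No probe of the array was named for GFP, so the transgene itself was not measured here.

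The main comparison asked which leukocyte genes differ between GFP transformants and wild type birds. Genes that fell most in the transformants included the developmental transcription factors PAX9, HOXA9, TWIST1 and TBX18, and the dopamine receptor DRD2. PAX9 fell by 2.14 on the log2 scale (SE 0.22, adjusted p = 0.00578 in limma), from -1.30 ± 0.43 to -3.44 ± 0.06 (SD, n = 3 in each group). EEF1A2, an elongation factor of neurons and muscle, fell by 1.93 (SE 0.14, adjusted p = 0.00384), and DRD2 fell by 1.80 (SE 0.11, adjusted p = 0.00256). TBX18 fell by 1.51 (adjusted p = 0.00578). HOXA9 fell by 1.61 and HHATL by 1.58 (adjusted p = 0.00683 and 0.00525), but they were well above background on only 2 and 1 of the 3 transformant arrays. Lower too were the lens crystallin CRYGS, which fell by 1.47, and the brain proteoglycan NCAN, which fell by 1.47, with adjusted p-values of 0.00937 and 0.00404.

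C11orf70, TWIST1 and the smooth muscle actin ACTA2 were not well above background on any of the 3 transformant arrays. For C11orf70 and ACTA2 only a bound of the fold can be given. Against the lowest signal well above background on each array, C11orf70 was at least 2.30-fold lower in transformants (adjusted p = 0.00384 in limma) and ACTA2 at least 1.79-fold lower (adjusted p = 0.0103). TWIST1 lay above that lowest signal on each transformant array, although not flagged as well above background. Its 2.94-fold fall (adjusted p = 0.0316 in limma) is therefore the fold of the signals as measured. It still rests on transformant signals that were not well above background.

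Named genes that rose in the transformants were 10 in number. CBL, a ubiquitin ligase that dampens receptor signalling, was not well above background on any wild type array and was at least 1.52-fold higher in transformants (adjusted p = 0.0137), and the myosin light chain MYL4 was at least 1.22-fold higher (adjusted p = 0.0144) on the same terms. SMAD7B and the zinc finger gene PLAG1 rose by 1.23 and 1.21, the latter with SE 0.21 and adjusted p = 0.0292. ST3GAL5, which makes the ganglioside GM3, rose by 0.84 (SE 0.15, adjusted p = 0.0281) and was well above background on 1 of 3 wild type arrays, and HMGN2P46 by 0.75 (SE 0.14, adjusted p = 0.0357). Smaller rises were measured for the sorbitol dehydrogenase gene SORD (0.58), CBY1 (0.56) and SAP130 (0.46), with adjusted p-values of 0.0352, 0.0486 and 0.0494. Next by unadjusted p came MAFK, at 0.70 (SE 0.14, adjusted p = 0.0511), and the chromatin remodeller CHD7, at 0.61 (SE 0.13, adjusted p = 0.0519), neither of which passed the test.

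**Figure D1:**
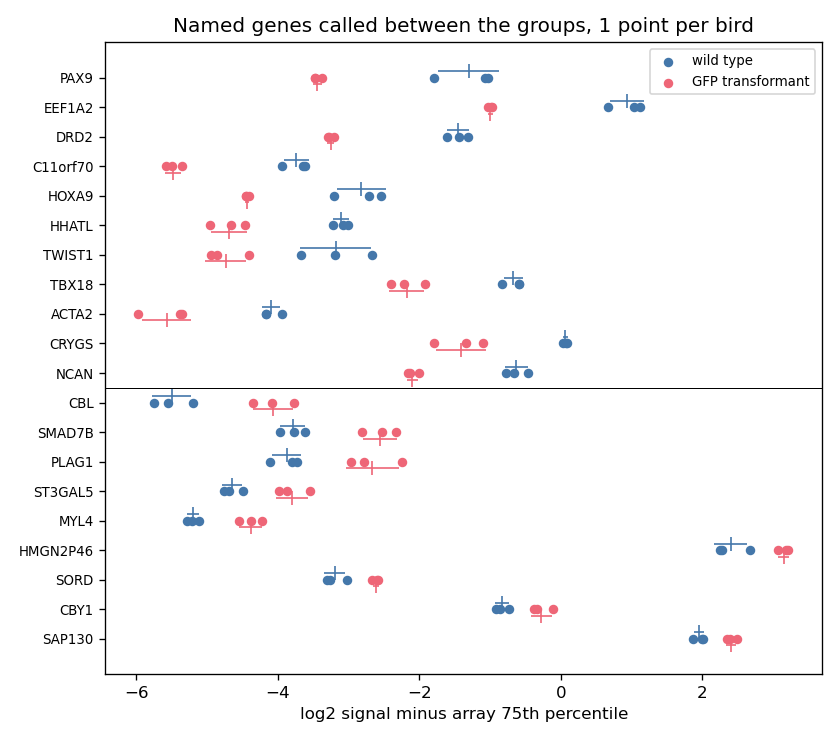
Log2 signal relative to each array's 75th percentile (x axis) of named genes that fell most (above the line) and of named genes that rose (below it), with 1 point per bird and crosses at the mean ± SD of the 3 birds of a group. PAX9 lies at -1.30 in wild type and -3.44 in transformants, and the groups do not overlap for any gene drawn.

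Over all 22988 features tested, 1216 differed at an adjusted p under 0.05 in limma, 1112 of them lower and 104 higher in the transformants. Named genes made up 149 of the lower and 10 of the higher features, out of 4356 named genes tested. At an unadjusted p under 0.05 there were 5048 features, against 1149 expected if no feature differed, but the split of wild type 2 with GFP transformants 1 and 2 against the other birds gave 4676. Of the 5048, 2764 were lower and 2284 higher. Median changes were small, at -0.85 for the features called lower and 0.65 for those called higher, and 388 of the lower and 19 of the higher features changed at least 2-fold. Below the median signal lay 803 of the features called lower, or 72.2%, while 907 of the 1112 were well above background on all 6 arrays. Without a single array the count fell to 368 (wild type 1), 553 (wild type 3), 706 (GFP transformant 2) and 658 (GFP transformant 3), and without wild type 2 the split became 972 lower and 516 higher. Of 27 passing genes followed by name, 16 no longer passed without wild type 1 and 15 without wild type 3. With the replicate number as a block 760 features were called, and 15 of the 27 genes no longer passed. With array weights 3157 features were called, 1868 lower and 1289 higher.

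**Figure D2:**
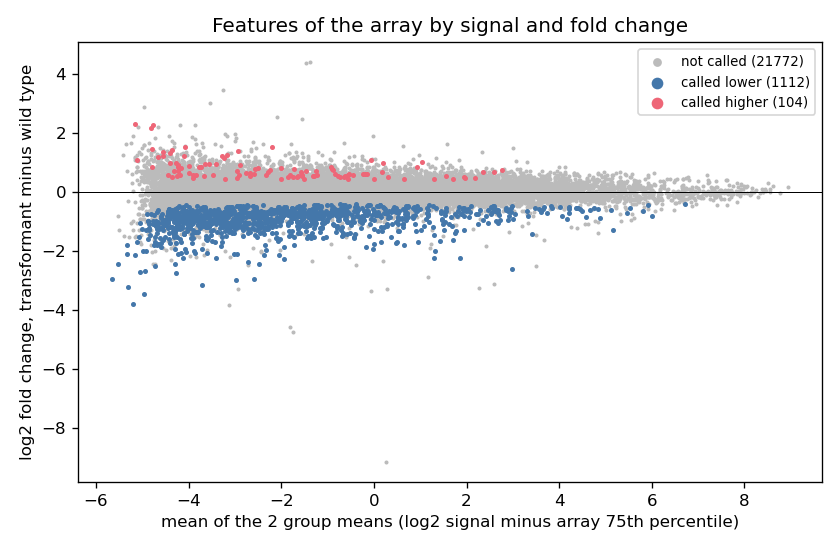
Log2 fold change of transformants over wild type (y axis) against the mean of both group means of the log2 signal (x axis), with 1 point per feature. Most of the coloured points, 1112 of 1216, lie below zero, and more of them lie on the dim side.

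The array carries several probes for many genes, and the probes of a called gene often disagreed. Of the genes called lower, 47 had other tested probes, 72 in all. The called probes of these genes changed by a median of -0.79 and the other probes by a median of -0.12, and 22 of the 72 other probes changed the opposite way. Over every probe tested on its own, 11 of the 72 were also called lower. SPP1, which encodes the secreted phosphoprotein osteopontin of activated macrophages, was lower on all 3 of its probes, at -0.68 and -0.85 on the other 2, which did not pass over every probe (adjusted p = 0.205 and 0.0808). EEF1A2 had another probe at -3.10 and a dim one at -0.01. The class II antigen presentation gene DMB1 stood at 0.57 on the named probe and fell by 1.61 on the other (adjusted p = 0.00543 over every probe). Genes named without a call are given on a single probe too, and their other probes followed it to a varying degree. Other probes ran from 0.04 to 0.43 for CHD7 and from -0.78 to 0.64 for LOC427025. They were at -0.14 and 0.25 for TAP1 and at -0.04 for H2AFZ. Others lay close to the named probe, as at 1.19 for GPX3 and -0.28 for RPS24.

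**Figure D3:**
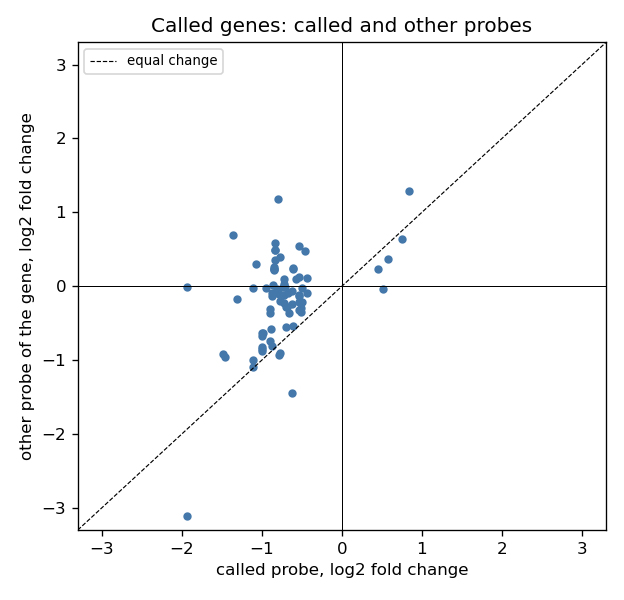
Log2 fold change of the other tested probes of a called gene (y axis) against that of its called probe (x axis), with 1 point per other probe and a dashed line of equal change. Most points lie nearer to zero than the line, with medians of -0.79 for called and -0.12 for other probes of genes called lower.

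The series design says that each triplet was compared by brute force, read here as a difference of at least 2-fold in all 9 pairs of a transformant and a wild type bird. Genes that met this in the named set were all lower in transformants, 16 in number by measured signal, among them EEF1A2, DRD2, PAX9 and the homeobox gene LMX1A. The smallest difference among the 9 pairs was 1.63 on the log2 scale for EEF1A2, 1.59 for DRD2, 1.58 for PAX9 and 1.24 for LMX1A. C11orf70 and ACTA2 met it only by signals not well above background, and with such signals set to each array's limit the named genes were 14. Over all features the count was 168 lower and 4 higher, or 134 lower and 0 higher at these limits, and the 2 groups did not overlap for 6332 of the features tested (27.5%), while the split of wild type 2 with GFP transformants 1 and 2 against the other birds gave 6316. With wild type 2 left out, 323 features were 2-fold apart in the remaining pairs. The count over all features, 172 in both directions, was 52 after normexp, 105 with signal on all 6 arrays and 263 without a filter. The offset added in normexp shrinks the folds behind this count by itself.

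By group means, 632 features were at least 2-fold apart with an unadjusted p under 0.05 in limma, 495 lower and 137 higher in the transformants. PAX9, EEF1A2, DRD2 and HOXA9 were among the lower ones, and SMAD7B and PLAG1 among the higher ones. This rule has no correction for the number of features tested. After normexp background correction the count was 179, after a filter for signal on all 6 arrays 375, and without a filter 1229. The 179 cannot be laid to the background alone, since the offset added in normexp shrinks the folds of dim features.

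Some genes were well above background on all 3 arrays of a group and on none of the other group. CBL, the receptor signalling antagonist SPRY2 and the junction protein gene F11R were the brightest named genes found in the transformants alone, at mean levels of -4.07, -4.07 and -4.11. They were at least 1.52-fold, 1.48-fold and 1.48-fold above wild type, where the limit or a higher own signal was used. TWIST1, C11orf70 and the growth factor gene FGF3 were found in the wild type birds alone, at -3.18, -3.74 and -3.94. FGF3 was at least 1.85-fold above transformants on the same terms. In all, 139 genes or unnamed probes were detected in the transformants alone and 104 in the wild type birds alone, of which 13 and 9 were named. The lowest signal well above background was lower on the transformant arrays on average, 8 of the 139 have no bound, and 2 of these were brighter in wild type, while a flag for positive and significant signal gave 102 and 104. Without wild type 2 the total rose from 243 to 551, without GFP transformant 1 to 445 and without GFP transformant 2 to 373.

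Thrombocyte genes, those of the nucleated counterpart of platelets, had a higher mean in the transformants for all 13 tested members, by a median of 0.46. By camera over 24 lists the adjusted p was 0.0248 with a preset correlation but 0.991 with an estimated one, and fry gave 0.933. The other 9 splits of the birds gave from 2 to 16 lists by the same camera test. None of the members passed alone over all genes. LY6E was 2.82-fold higher on its named probe (SE 0.31 on the log2 scale, adjusted p = 0.0524) and at a log2 change of 1.42 on the other, the transcription factor GFI1B, well above background on 2 of 3 wild type arrays, at 1.07 (SE 0.34), and the integrin ITGB3 at 0.44 (SE 0.18). Adjusted over the list alone, 1 member passed. The call was lost without wild type 3 (median 0.28, adjusted p = 0.276) or without GFP transformant 2 (median 0.20, adjusted p = 0.237).

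Oxidative phosphorylation genes had 29 of 35 tested members lower, with a median of -0.13 and a camera adjusted p of 0.0414 with a preset correlation but 0.991 with an estimated one. No member passed alone, over all genes or adjusted over the list alone. The ATP synthase genes ATP5I and ATP5C1 were at -0.45 (SE 0.12) and -0.41 (SE 0.14), NDUFA9 of complex I at -0.32 (SE 0.10) and SDHD of complex II at -0.31 (SE 0.11). Their other tested probes were lower by less. These were at -0.15 and -0.26 for ATP5C1, at -0.02, -0.14 and -0.12 for NDUFA9 and at -0.22 for SDHD. The call of the oxidative phosphorylation list was lost with quantile normalization (adjusted p = 0.0679), median scaling (0.0818), no filter (0.253), the deposited table of the series (0.0569), normexp (0.110) and exact symbols (0.0534). It was also lost without wild type 1, wild type 3, GFP transformant 1 or GFP transformant 2 (adjusted p = 0.154, 0.445, 0.175 and 0.237).

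The other cell type lists did not pass, and the birds of a group differed widely in some of them. Heterophils are the avian counterpart of neutrophils, and the mean of their 17 tested genes was 1.13 above the average of the 6 birds in wild type 3 and 1.11 above it in GFP transformant 3, while the remaining birds lay between -0.87 and -0.31 (camera adjusted p = 0.918 between the groups). S100A12, a granule protein gene of this list, was at 4.48 ± 0.67 in wild type and 2.86 ± 1.65 in transformants (SD, n = 3), and EXFABP differed by -0.45 (SE 0.24). T cell genes had a median of 0.04 (adjusted p = 0.918), with IL7R at 0.32 and CTLA4 at -0.47. B cell genes had 12 of 13 members higher, with a median of 0.22 (adjusted p = 0.375), TNFSF13B being at 0.22 and IRF4 at 0.25. Natural killer and cytotoxic genes had 7 of 8 higher, with a median of 0.30 (adjusted p = 0.375), NCAM1 at -0.43 and the chemokine CCL5 at 0.64. In the monocyte and macrophage list (median 0.06, adjusted p = 0.918) SPP1 fell by 1.00 (SE 0.14, adjusted p = 0.0136), the only member to pass over all genes or adjusted over the list alone, and the endotoxin co-receptor CD14, well above background on 2 of 3 wild type arrays, was at 1.06 (SE 0.44, adjusted p = 0.228). Erythroid genes had a median of 0.10 (adjusted p = 0.795), with the globin gene HBBR at -0.77 (SE 0.43) and the linker histone gene H1F0 at 0.29, and dendritic cell genes a median of -0.01 (adjusted p = 0.991), with CD86 at -0.29 and CCR7 at 0.11.

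**Figure D4:**
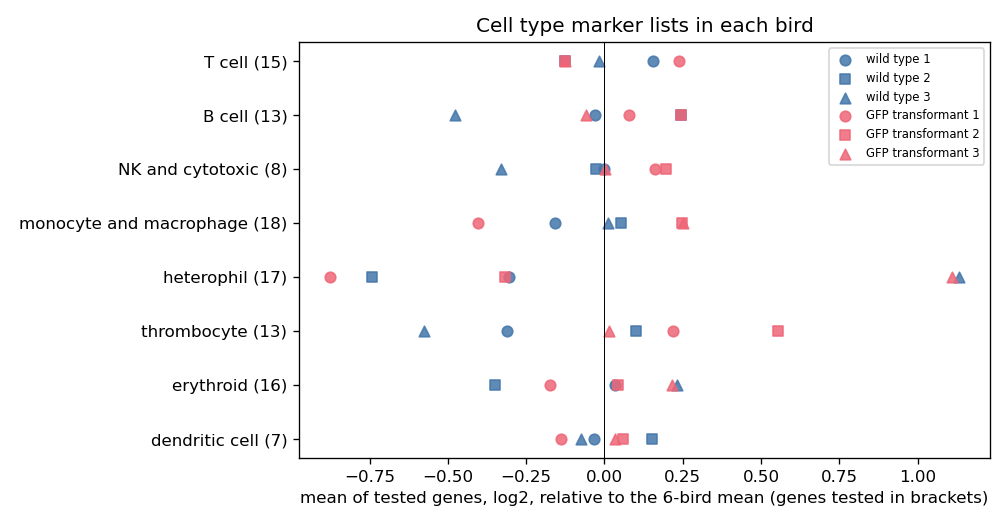
Mean log2 level of the tested genes of each cell type list in each bird (x axis), relative to the mean of the 6 birds, with blue for wild type, red for GFP transformants and a symbol for each replicate. The heterophil list spans -0.87 to 1.13 and has a bird of each genotype at its upper end.

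Among immune pathways, the chemokine genes CXCL14 and CCL1 fell by 0.71 (SE 0.11, adjusted p = 0.0183) and 0.87 (SE 0.17, adjusted p = 0.0401), as the only members of 29 in the inflammatory list to pass over all genes or adjusted over the list alone. The list as a whole had a median of -0.01 (camera adjusted p = 0.918). Interferon response genes had 13 of 21 members higher, with a median of 0.16 (adjusted p = 0.549), TAP1 at 0.32 and IRF1 at 0.38, and none passed alone. The antigen presentation list (median -0.07, adjusted p = 0.918) held BLEC1 at -0.75 (SE 0.17, adjusted p = 0.0642). Innate sensors had a median of -0.03 (adjusted p = 0.918), with IRF7 at 0.22.

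Proliferation genes had 25 of 29 members lower, with a median of -0.21 (camera adjusted p = 0.375), but CDC20 was at 0.49 (SE 0.15) and TOP2A at -0.58 (SE 0.32). The mean of this list ran from -0.40 in wild type 2 to 0.47 in wild type 3. Replication histone genes had a median of -0.02 (adjusted p = 0.918) with H2AFZ at -0.36, and ribosomal protein genes a median of -0.07 with 39 of 51 lower (adjusted p = 0.186), RPL26L1 and RPS24 being at -0.25 and -0.29. Immediate early genes had 13 of 14 members higher, with a median of 0.22 (adjusted p = 0.129), CYR61 at 0.60 (SE 0.18) and MYC at 0.59 (SE 0.19). In none of these lists did a member pass, over all genes or adjusted over the list alone.

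In the glycolysis and hypoxia list (median -0.07, adjusted p = 0.647) the lactate transporter SLC16A3 was at 0.53 (SE 0.16). Over all genes, and adjusted over the list alone, 1 member passed. Stress lists had medians of -0.04 for the unfolded protein response (adjusted p = 0.795), 0.16 for heat shock (0.647), -0.05 for oxidative stress (0.918) and 0.04 for p53 and apoptosis (0.991). Their members with the smallest p were CRELD2 and PDIA4 at -0.43 and -0.38, HSPE1 and HSPB9 at -0.40 and 0.81, GCLM and GPX3 at -0.48 and 1.13, and CHEK1 and FAS at -0.51 and -0.50. Proteasome genes had a median of -0.12 (adjusted p = 0.375), PSME4 being at 0.53 and PSMC3 at -0.20, and cholesterol synthesis genes a median of -0.21 (adjusted p = 0.554), MSMO1 being at -0.40 and ACAT2 at -0.18. None of the members of these last 6 lists passed, over all genes or adjusted over the list alone.

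Of 443 distinct list genes tested, 4 passed over all genes, among them SPP1, CXCL14 and CCL1, all lower in transformants. By camera 2 of the 24 lists passed, and 4 had an unadjusted p under 0.05. With an estimated correlation 0 lists passed and 0 had an unadjusted p under 0.05, and the same counts of 0 were given by fry, which tests whether the genes of a list move one way on balance. The median and the mean differed in sign for the T cell, heterophil, innate sensor, oxidative stress and p53 lists. The direction given by camera opposed the median for the heterophil, antigen presentation, innate sensor, replication histone and p53 lists.

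Between birds, the levels of the tested features correlated, across features that are not independent replicates, with a Pearson r of 0.979 to 0.989 within wild type, 0.982 to 0.984 within transformants and 0.969 to 0.982 between them. The mean squared log2 difference was 1.51 times as large between groups as within them. In an exact test over all 10 splits of the 6 birds, no other split gave as high a ratio, a share of 0.1, which is the smallest that 3 against 3 allows.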

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

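The normexp forms, the restriction to named genes or to the brighter features, the lists with exact symbols only and the signals set to a limit were chosen after the data were seen. The count of 1216 features stayed within 1.5 times under the other scalings, filters, variance models without weights, probe rules, deposited values and detection flag, between 1027 and 1360, and lower features outnumbered higher ones in each. The deposited values differ from the main ones only in their scaling. A signal floor of 5 units left the count at 1216, with 1112 lower and 104 higher, and so tested nothing further. The count was 3157 with array weights. Testing only the 4356 named genes gave 151, where the main fit had called 149 of them lower and 10 higher. Testing only the 11494 brighter features gave 337, where the main fit had called 309 of them lower and 31 higher. The count over all features was 0 with normexp on local backgrounds as they stand. There, 1644 features had an unadjusted p under 0.05 and a spot background reached 63161 units. With flagged backgrounds replaced, the count was 1232. The fit with the replicate number as a replicate block called 760 features. Whether the numbers pair the birds is not settled. Deviations from the group means correlated at -0.01, 0.38 and 0.31 between the birds numbered 1, 2 and 3. Birds numbered 2 and 3 correlated best with the bird of their own number, and those numbered 1 did not. The number also followed the position of the array on its slide. Leaving out a bird gave 368 to 1488 features.

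The count of 632 features 2-fold apart in means became 1229 without a filter, 375 with signal on all 6 arrays and 179 after normexp, and 545 to 900 with a bird left out. The count of 172 over all 9 pairs became 263, 105 and 52 under these settings, and 194 to 323 with a bird left out, which leaves fewer pairs, and it was 134, all lower, with signals under each array's limit set to it. Both counts after normexp also reflect its added offset, which shrinks the folds of dim features. Genes detected in a single group numbered 318 to 551 with a bird left out, which asks for fewer arrays. Of the 24 lists, 2 passed in the main setting, 1 with quantile normalization, median scaling, the deposited table, normexp or exact symbols, 4 with the replicate block, 5 with array weights, 0 with an estimated correlation or fry, and 0 to 4 with a bird left out. The ratio of spread between and within groups kept its direction in its 4 alternatives.

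Of the passing genes, the 27 chosen by the naming rule of the text were followed, and none of these changed direction in any alternative run on them. Of these 27, 16 no longer passed without wild type replicate 1, 15 without wild type replicate 3 and 15 with the replicate block, and over all alternatives 335 values stayed past the threshold and 115 did not. Of the others, HINTW changed sign with array weights (-0.0559) and with the mean of its probes (-0.12), and ran from -0.11 to 0.12 with a bird left out. DMB1 turned to -0.52 with the mean of its probes, HNRNPKL to 0.0163 without wild type replicate 1, and CCR7 to -0.0237 after normexp, and none of these values passed. The causes of these changes were not tested, apart from the fewer features or birds that a setting leaves. A block for slide and normexp on mean signals were not run. Signal over background limits the dim genes, since a fold of a gene that is not well above background in a group is a bound or rests on such a signal.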

Other observations

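The tests of scaling, background, other probes, list correlations and families below, and the counts over splits, were chosen after the results they bear on were seen. The tests of places on the slide and of neighbouring genes were not. The prediction for families within bins of signal was written before its result, but for families picked from the genes called. The name pattern of the families was corrected 2 times after results were seen. Of 36 tested genes named for homeobox, forkhead, T-box, SOX and paired families, 14 were called lower in the transformants and 0 higher, where limma gave a median change of -0.42 for the families. Besides PAX9, HOXA9, TBX18 and LMX1A these included HOXB1 (-1.24), POU1F1 (-1.15), BARX1 (-1.08), FOXD2 (-1.08), CDX1 (-0.99), OTX5 (-0.84), IRX1 (-0.75) and ALX4 (-0.61), genes chosen after their values were seen. Of the other 4320 named genes 135 were called lower, against 38.9% of the families (Fisher's exact one-sided p = 3.24e-12). Earlier patterns held bHLH families such as TWIST1, and gave 12 of 27 without the HOX and FOX genes (exact p = 1.84e-11, stratified 3.95e-08) and 15 of 38 with them (3.99e-13, stratified 3.29e-09). Of the 36 genes, 24 lay in the dimmest of 5 bins of signal, but within these bins the families still held more lower calls (stratified exact one-sided p = 1.47e-08). Since the families were picked from the names of the genes that fell, neither test decides between a change of developmental genes and dimness of their probes, and both stay open. A sequence property that these probes share may contribute and stays open too, since probe sequences were not used here.

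The excess of features called lower, 1112 against 104, was weighed against technical explanations, although it was smaller by looser measures, with 2764 lower and 2284 higher at an unadjusted p under 0.05 and 3440 and 2892 without overlap, and with array weights, at 1868 and 1289. Other scalings argue against the scaling as its cause, since the fewest lower calls were 1032. Damage in places is argued against by neighbouring spots being called 1.10 times as often as after shuffling. Lower calls outnumbered higher ones by 309 to 31 in the brighter features (ratio 9.97) and by 803 to 73 in the dimmer ones (ratio 11). Background near the dim end alone would thus leave the excess in the brighter features unexplained. Its contribution among the dim features stays open, since most lower calls lay there. After normexp 1023 features were called lower and 209 higher. Those 2-fold apart in means fell from 632 to 179, but the offset added in normexp shrinks the folds of dim features by itself. That fall therefore does not decide on the background. Other probes of the called genes changed by a median of 0.215 times the called probe (95% bootstrap interval over genes 0.0313 to 0.406), while for the same number of top genes in the other 9 splits of the birds this ratio was between 0.805 and 0.976, which argues against changes of whole transcripts as the source of the called named genes as a set. A difference in how single probes hybridised on the slides is in line with this, and the control spots named bright corner also differed between the slides, at 4.95 ± 0.06 and 4.07 ± 0.11 (SD, n = 3 arrays each), and the 8 spike-in controls above the level of the negative controls were lower in the transformants by -0.59 to -0.01. The negative controls themselves differed by -0.28. Slide and genotype cannot be told apart here, and changes in parts of transcripts and in the genes whose probes moved together, such as SPP1, AQP2 and MED27 (chosen after their values were seen), remain open.

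Over the 10 splits of the 6 birds into 3 and 3, too few for a share under 0.05, the split by genotype alone (1 of 10) gave as many called features (1216, highest other 4), as many features 2-fold apart in all 9 pairs (172, highest other 28), as many 2-fold apart in means (632, highest other 292) and as many genes detected in a single group (243, highest other 123). By looser measures another split, of wild type 2 with GFP transformants 1 and 2, came near it, with 4676 against 5048 features at an unadjusted p under 0.05 and 6316 against 6332 features without overlap. For lists called by camera, all 10 of 10 splits gave at least the 2 of the genotype split, and the highest other gave 16.

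The birds differed in heterophil and proliferation genes within both groups. The means of both lists correlated over the 6 birds with a Pearson r of 0.811 (exact permutation p = 0.0653, adjusted 0.0979 over 3 relations) and a Spearman rho of 0.771 (exact p = 0.103, adjusted 0.103). Without wild type 3 and GFP transformant 3, the birds farthest from the median, r was 0.524, so its size depends on these birds, and each slide held too few birds for a value of its own. Thrombocyte and proliferation means had an r of -0.852 (exact permutation p = 0.0236, adjusted 0.0708) and a rho of -0.829 (exact p = 0.0583, adjusted 0.103), with an r of -0.737 without the farthest birds, wild type 3 and GFP transformant 2, and thrombocyte and heterophil means had an r of -0.552 (exact p = 0.254, adjusted 0.254) and a rho of -0.771 (exact p = 0.103, adjusted 0.103), with -0.246 without the same birds. A varying share of heterophils or of immature cells at the gradient's interface may lie behind this, although the gradient is meant to keep most granulocytes from the interface, and 6 birds do not decide it.

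Called genes were next to each other along the chromosomes about as often as in random draws. Among 4406 tested genes in the order of the gene table, 167 were called and 9 pairs of called genes were neighbours, against a mean of 6.2 over 10000 random draws and a 95th percentile of 10 (one-sided permutation p = 0.168), although a single site with few genes would not be seen by this count.

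With signals under each array's limit set to it, a step added after the first count, the birds fell apart in 15 features into a low and a high set with a gap of at least 8-fold, and 0 of these gaps ran between the genotypes. The only named gene among them was ERNI, low in wild type 1, wild type 3 and GFP transformant 1, with a gap of 3.99 on the log2 scale. By measured signal, gaps of at least 8-fold between the genotypes did occur. Unnamed probes lower in the transformants had such gaps of 3.38 and 3.08 on the log2 scale. These probes were not well above background on any transformant array, and were at least 3.11-fold and 3.27-fold lower there. In fry's test for change in either direction, 2 of the 24 lists passed, the natural killer and antigen presentation lists.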
